A study of Mus musculus with 5 samples.

How the data were processed

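Gene expression was measured by RNA sequencing in kidneys of 5 C57BL/6 mice, 3 after cecal ligation and puncture (CLP) and 2 after a sham operation. CLP is a model of sepsis in which the cecum is tied off and pierced, here with a 22-gauge needle, so that gut content leaks into the abdomen. Sham mice had surgery in which the cecum was neither tied nor pierced. Kidneys were collected 6 hours after CLP, and a separate interval for the sham mice is not given in the sources used here. The series' design text describes 5 mice, so that each library stands for a mouse, and the replicate numbers only name them. Per the labels' protocols, 1 µg of total RNA per kidney was depleted of ribosomal RNA, prepared with a directional kit and read as 150 bp pairs on a NovaSeq instrument.

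The authors deposited a table of estimated counts (expected counts that need not be whole) for the 5 kidneys. They also deposited FPKM values, which are counts scaled to length and depth by the authors, for each kidney. Per the submitters' processing notes, fastp 0.20.0, Bowtie2 2.3.1, eXpress 1.5.1 and the build mm10 were used; the role of each, the annotation release and the strand setting of the counting are not given in the sources used here. The count table held 76203 rows under 21990 numeric gene IDs, with a median of 2 rows per ID and no transcript identifier. Of the row values, 24.1% were whole to within 1e-06. In rows above 100 counts in every library, the ratio of count to FPKM was a row constant times 1 factor per sample, to within 0.000182%, so the FPKM values are not independent of the counts.

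Expected counts were summed per gene ID and rounded to whole numbers. The test had been planned for counts and was kept for these rounded values. Where strand was not used, reads of overlapping and antisense genes could not be told apart. Symbols, biotypes and coordinates were taken from the RefSeq annotation of GRCm38.p6, the assembly known as mm10. It matched 21823 of the 21990 IDs, and the other 167 were kept under their ID. The unmatched IDs held 1.99% to 2.11% of counts in the CLP libraries and 0.444% and 0.881% in the sham libraries. Library totals were 27.4, 24.1 and 23.1 M counts for CLP 1, 2 and 3, and 23.8 and 21.5 M counts for sham 1 and 2. A count of 0 in a library allows a level of up to 0.111 to 0.145 CPM, taking a floor of 3 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

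The comparison of CLP with sham used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, TMM factors and the default expression filter by group. The fit had no covariate. Adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05. The samples left 3 residual degrees of freedom, and a median of 8.43 after information was pooled across genes. The SE of a log2 fold change is its size divided by the square root of F. Levels are counts scaled to a library of 1e+06 (CPM) with TMM factors, given as mean ± SD, with n = 3 for CLP and n = 2 for sham throughout. Where a group held no count, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with its 95% counting interval.

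Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and 2-sided p, adjusted over the 35 lists with at least 5 tested members. The 39 lists were acute phase, NF-kB feedback and subunits, chemokines, cytokines, interferon-stimulated, cytokine receptor and STAT3 feedback, innate sensing, complement, immediate early, endothelial activation and coagulation, tubular injury, proximal tubule transporters, fatty acid oxidation, nuclear OXPHOS subunits, cholesterol synthesis and uptake, metallothionein and oxidative stress, hypoxia response, ER stress and ATF4 targets, heat shock, glucocorticoid response, circadian clock, inflammasome and cell death, iron handling, proliferation, sex-specific genes and structural non-coding RNA, and markers of thick ascending limb, distal and connecting tubule, collecting duct, podocytes, endothelium, stroma and mural cells, neutrophils, monocytes and macrophages, lymphocytes, erythroid cells and platelets, adipocytes, adrenal, and pancreas, liver and gut. They hold 688 entries, some shared between lists, and 19 symbols were not found among the matched IDs. With a correlation estimated per list, none of the 35 lists passed, and the smallest adjusted p was 0.464. The rotation test fry asks whether the members of a list move 1 way on balance, without comparing them with other genes. By its directional p, 14 lists passed as higher and 0 as lower, and by its mixed p 33 lists passed.

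The design, the lists, the rule for named genes and all alternatives except loess scaling were fixed before the data were examined. Named genes were the 10 largest fitted changes in each direction among called genes, up to 3 called members of each list by smallest p, and 15 fixed genes. The first part required a mean of at least 1 CPM, groups that did not overlap, and a symbol that is not a clone or model name. Where a list had no called member, its 2 most abundant members were taken. This gave 126 genes, of which those that describe each group are named. Further members named beside them were chosen after their values were seen. A few members that the rule selected are not reported here. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, each library left out in turn, replicate number as a block, the deposited FPKM values with limma, a fold threshold and the rows as deposited.

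On simulated counts for the CLP and sham comparison, with 14164 genes tested, the edgeR fit recovered 14.0% of 100 genes changed 2-fold and 68.7% of 99 genes changed 4-fold. It called 20 of 13926 unchanged genes. In simulated lists of 20 genes, camera called 2 of 2 lists changed 2-fold and 0 of 40 unchanged lists. Camera with an estimated correlation called 0 of the 2 changed lists. The simulated genes were drawn independently, so these counts do not test the preset correlation of 0.01 on correlated genes. In the 35 lists tested, the estimated correlation ran from 0.0467 for innate sensing to 0.871 for interferon-stimulated genes. Most changes of 2-fold size were thus missed in the simulation. It changed far fewer genes than the 3379 called in the data, and the adjusted p depends on that number. The shares recovered need not hold for the data.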

Results

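The data comprised 5 kidney transcriptomes from C57BL/6 mice, 3 taken after cecal ligation and puncture (CLP) and 2 after sham operation. Kidneys were taken 6 hours after CLP, and a separate interval for the sham operation is not given in the sources used here. The comparison asks which transcripts differ in the kidney between septic and sham-operated mice. Totals per library lay between 21.5 and 27.4 M counts (M, 1e+06), and 15228 to 15992 genes had a count above 0. The CLP and sham libraries separated along the first principal component of log2 CPM, which held 70.8% of the variance, with scores of -26.5, -68.7 and -84.5 for CLP 1, 2 and 3 and of 73.6 and 106 for sham 1 and 2. The 50 most abundant genes took 15.9% to 16.9% of counts in CLP and 14.7% and 12.5% in sham.

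By camera with a preset correlation, kidneys from CLP mice carried more mRNA for lists of acute-phase, cytokine-response, immediate early and tubular injury genes. By the same test they carried less for transporters of the proximal tubule and for markers of thick ascending limb, collecting duct, endothelium and stroma. With an estimated correlation no list passed (smallest adjusted p = 0.464), the rotation test fry called 0 lists lower, and the proximal tubule list missed the threshold without sham 1 (camera adjusted p = 0.214). Of 14379 genes tested, 1774 were higher and 1605 lower in CLP (edgeR adjusted p under 0.05), so that 52.5% of the calls were higher. Among them, 1342 were at least 1 log2 unit higher and 1314 at least 1 log2 unit lower. In all 3379 the CLP and sham kidneys did not overlap, as was the case in 58.9% of all genes tested against 20% by chance for 3 against 2. The number of calls was 633 higher and 432 lower without CLP 2, against 1955 and 1933 without CLP 1 and 1261 and 1162 without CLP 3. It was 1153 and 848 without sham 1 and 536 and 382 without sham 2. These last fits hold 1 sham kidney, which is assumed to vary like the CLP kidneys, so that fewer calls follow from the design as well. Of 115 called genes selected by the naming rule, 43 had a fold that moved by over 1.5 times when 1 kidney was left out. Scaling by library size alone gave 1169 higher and 2464 lower (32.2% higher), with the median of all genes at -0.34 instead of -0.04, and the FPKM values with a pseudocount of 1 gave 1335 and 2167 (38.1% higher), with the median at -0.18. The median log2 fold change also rose with abundance, from -0.73 in the 2876 genes of lowest mean CPM to 0.31 in the 2876 of highest.

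**Figure D1:**
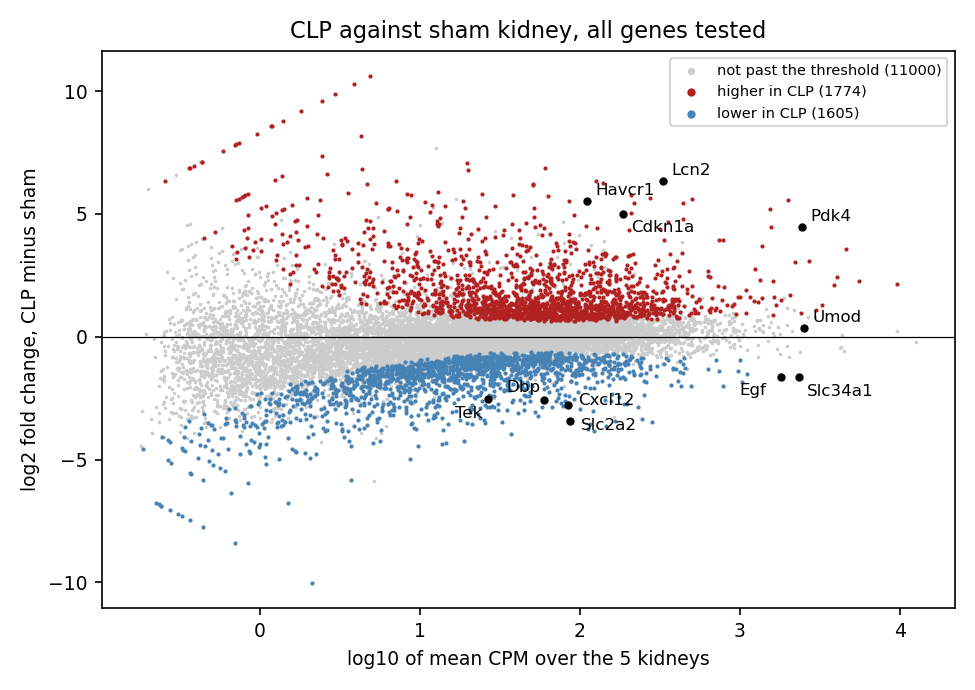
Each point is 1 of the 14379 genes, with the log10 of its mean CPM over the 5 kidneys on the x axis and its fitted log2 fold change, CLP minus sham, on the y axis. Red marks the 1774 genes higher, blue the 1605 lower, and grey the rest. Black points with a symbol run from Lcn2 at 6.34 to Slc2a2 at -3.44, and fitted values of genes at 0 in a group, which form the slanted lines, depend on the prior count.

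Among the largest increases were 8 genes with no count in either sham kidney. Serpina3m, a serine protease inhibitor of the acute-phase family (gene ID 20717, chromosome 12, 104387157 to 104394259, mm10), was at least 139-fold higher. The bounds were 110 for the epithelial gene Sprr2f, 84.4 for the neutrophil protein S100a9, 69.3 for the glutathione transferase Gsta1, 51.6 for Cd300lf, 39.6 for Lilr4b, 34.0 for the interleukin 1 family member Il1f9 and 33.6 for the myeloid receptor Trem1. Il1rn, the interleukin 1 receptor antagonist, and the matrix protease Mmp7 had 1 sham count each, with ratios of 204 (95% interval 36.3 to 8085) and 335 (59.9 to 13270). Several of these rested on CLP 3, without which the bounds were 25.1 for Gsta1, 13.9 for Il1f9, 85.7 for Serpina3m, 69.9 for Sprr2f and 32.1 for Cd300lf, and the ratio of Mmp7 was 130 (22.9 to 5187). Without sham 1, Il1rn and Mmp7 had no sham count and were at least 35.4-fold and 61.4-fold higher. Leaving out either sham kidney raised the floor of all bounds, and that of Serpina3m was then 68.6 at the lowest. Among the largest decreases, Trdn, a calcium release protein of muscle, had no count in CLP and was at least 123-fold lower, although its sham level was uneven, at 9.83 CPM in sham 1 and 0.847 CPM in sham 2, with a bound of 19.5 without sham 1. Csrnp3 fell from 9.11 ± 2.65 to 0.149 ± 0.134 CPM, the apelin receptor Aplnr from 5.34 ± 1.02 to 0.180 ± 0.229 CPM, and Arhgef39 from 20.7 ± 1.04 to 0.634 ± 0.469 CPM. The others were Grin3a (log2 fold change -5.16), Ppp1r14a (-4.98), Unc13c (-4.92), Ahrr (-4.90), Slitrk6 (-4.73) and Ankrd65 (-4.71). Values for Serpina3m, Sprr2f, Gsta1 and Lilr4b are uncertain, since they belong to families of close copies between which the counting could split reads. Arhgef39 overlaps Car9, a gene named below, on chromosome 4 (43496139 to 43508747 and 43507026 to 43513729). Reads of the shared stretch could not be told apart where strand was not used. The calls of Gsta1, Il1f9, Mmp7, Trdn, Grin3a, Ppp1r14a, Ahrr, Aplnr, Slitrk6 and Ankrd65 were lost without single kidneys. Gsta1, Grin3a and Ppp1r14a lost theirs without CLP 2, sham 1 or sham 2, and Ahrr without CLP 3 or sham 2. Il1f9, Mmp7, Aplnr and Ankrd65 lost theirs without sham 1 or sham 2, and Slitrk6 without sham 1. Trdn lost its call without CLP 1, CLP 2, CLP 3 or sham 1. Without sham 1 the log2 fold change of Slitrk6 was -3.59, and without sham 2 that of Ahrr was -2.24.

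Of 15 tested acute-phase genes, 13 were higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 8.46e-10; adjusted p = 0.464 with an estimated correlation), with a median log2 fold change of 5.46. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2 (gene ID 16819, chromosome 2, 32384637 to 32387739), rose from 6.79 ± 2.74 to 551 ± 197 CPM, a log2 fold change of 6.34 ± 0.49 (SE; edgeR adjusted p = 0.00118). Lrg1 rose by 5.46 ± 0.37 (edgeR adjusted p = 0.000826) and Serpina3n by 3.31 ± 0.37. Of 18 genes for NF-kB subunits and their feedback inhibitors, 15 were higher and 0 lower (16 and 0 over the list alone; camera adjusted p = 7.16e-08; adjusted p = 0.464 with an estimated correlation), with the smallest p for Bcl3 at 4.05 ± 0.37, Birc3 at 3.17 ± 0.42 and Relb at 2.66 ± 0.38. Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, rose by 1.84 ± 0.37. Chemokines went both ways, with 7 of 18 higher and 2 lower (10 and 2 over the list alone; camera adjusted p = 0.00166; adjusted p = 0.464 with an estimated correlation). The neutrophil attractants Cxcl5 and Cxcl1 rose by 5.24 ± 0.61 and 5.67 ± 0.79, while Cxcl12 fell from 174 ± 28.1 to 25 ± 6.01 CPM. Of 15 cytokines, 8 were higher and 2 lower (11 and 2 over the list alone; camera adjusted p = 0.000176; adjusted p = 0.464 with an estimated correlation), with a median of 3.68, or 3.09 with Osm, the member at 0 in sham, at its bound. Il34, a ligand of the macrophage growth factor receptor, rose by 3.68 ± 0.31 and Il1b from 1.00 ± 0.490 to 15.9 ± 7.87 CPM. Tnf had 3 sham counts and a ratio of 31.4 (95% interval 10.5 to 154), while Il6 stood at 22.3 ± 20.4 against 0.889 ± 0.930 CPM and missed the threshold (edgeR adjusted p = 0.0613). The ratio of Tnf was 20.1 (6.55 to 100) without CLP 3 and 15.5 (5.17 to 76.0) without sham 2, and Cxcl1 was at 5.05 without sham 2. Tnf lost its call without CLP 2 or sham 2 and Nfkbia without sham 1 or sham 2 (highest edgeR adjusted p 0.129 and 0.0765), and Il6 passed without CLP 1 (0.0191).

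Cytokine receptor and STAT3 feedback genes were higher in 17 of 22 members and lower in 0 (18 and 0 over the list alone; camera adjusted p = 1.83e-09; adjusted p = 0.464 with an estimated correlation). Stat3 rose from 83.6 ± 8.80 to 578 ± 79.2 CPM, Cebpd, a transcription factor induced by interleukin 6, by 3.23 ± 0.33, and the tumour necrosis factor receptor Tnfrsf1b from 0.296 ± 0.310 to 33.3 ± 6.44 CPM. Immediate early genes were higher in 18 of 24 and lower in 0 (19 and 0 over the list alone; camera adjusted p = 7.16e-08; adjusted p = 0.464 with an estimated correlation). Among them were Fosl2 (4.33 ± 0.36), Maff (3.67 ± 0.40) and Klf6 (3.92 ± 0.54). Innate sensing genes were higher in 6 of 18 and lower in 0 (8 and 0 over the list alone; camera adjusted p = 0.0171; adjusted p = 0.464 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 rose from 16.8 ± 13.9 to 729 ± 360 CPM, the adaptor Myd88 by 2.48 ± 0.31 and Tlr2 by 3.49 ± 0.52. Without sham 2 this list missed the threshold (camera adjusted p = 0.0665). Of 24 interferon-stimulated genes, 23 had a positive fold change but only 4 were called higher, 0 lower, and none adjusted over the list alone (camera adjusted p = 6.77e-05; adjusted p = 0.583 with an estimated correlation). At an unadjusted p under 0.05 there were 16, and DESeq2 called 16 higher and limma-voom 4. Irf7, Oasl2 and Isg15 rose by 2.59 ± 0.65, 2.01 ± 0.57 and 2.81 ± 0.82, and each lost its call without sham 1 or sham 2 (highest edgeR adjusted p 0.145, 0.183 and 0.177). All 3 were highest in CLP 3, and without it the log2 fold changes were 1.77, 1.28 and 1.78, with Isg15 not called (edgeR adjusted p = 0.0998). Isg15 also lost its call without CLP 2. Complement genes showed no common direction, with 3 of 17 higher and 1 lower (3 and 1 over the list alone; median -0.27, mean 0.11; camera adjusted p = 0.998). C3 rose by 3.93 ± 0.90 and the receptor C5ar1 by 2.07 ± 0.54, each losing its call without CLP 2, sham 1 or sham 2 (highest edgeR adjusted p 0.0921 and 0.130). Without CLP 3 C3 was at 2.92, and without sham 2 Cd14 was at 4.77 and Tnfrsf1b at 5.99.

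Tubular injury genes were higher in 15 of 22 members and lower in 1 (15 and 1 over the list alone; camera adjusted p = 1.20e-07; adjusted p = 0.464 with an estimated correlation). Havcr1, which encodes kidney injury molecule 1 (gene ID 171283, chromosome 11, 46739822 to 46779578), rose from 4.02 ± 3.34 to 184 ± 112 CPM, a log2 fold change of 5.51 ± 0.94 (edgeR adjusted p = 0.0140). The cell cycle inhibitor Cdkn1a rose by 5.02 ± 0.38 (edgeR adjusted p = 0.000830) and Gdf15 by 4.18 ± 0.39. Inflammasome and cell death genes were higher in 7 of 20 and lower in 0 (7 and 0 over the list alone; camera adjusted p = 0.00848; adjusted p = 0.464 with an estimated correlation). Among them were Casp8 (1.65 ± 0.28), the anti-apoptotic Bcl2l1 (1.61 ± 0.28) and the pro-apoptotic Bcl2l11 (1.65 ± 0.32). None of 13 proliferation genes was called by edgeR, also adjusted over the list alone (camera adjusted p = 0.543), with 3 at an unadjusted p under 0.05, 3 called by DESeq2 and 2 by limma-voom. Pcna was at 66.5 ± 6.53 against 42.5 ± 6.62 CPM and Tyms at 16.8 ± 5.34 against 31.8 ± 5.47 CPM. Havcr1 lost its call without CLP 2 or CLP 3 (highest edgeR adjusted p 0.0638) and Casp8 without sham 2 (0.0664). Without sham 2 the log2 fold change of Havcr1 was 4.84.

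Targets of ER stress and ATF4 were higher in 9 of 19 and lower in 0 (12 and 0 over the list alone; camera adjusted p = 3.07e-05; adjusted p = 0.464 with an estimated correlation), with Psat1, an enzyme of serine synthesis, up from 31.7 ± 3.76 to 321 ± 69.3 CPM, Chac1 up by 4.23 ± 0.48 and Xbp1 by 2.43 ± 0.33. Metallothionein and oxidative stress genes were higher in 9 of 17 and lower in 0 (10 and 0 over the list alone; camera adjusted p = 6.59e-06; adjusted p = 0.464 with an estimated correlation). Mt2 rose by 4.69 ± 0.43, Mt1 by 3.96 ± 0.48 and the cystine transporter Slc7a11 by 5.83 ± 0.75. Iron handling genes were higher in 7 of 13 and lower in 0 (10 and 0 over the list alone; camera adjusted p = 6.52e-05; adjusted p = 0.464 with an estimated correlation), with the metalloreductase Steap4 and the metal importer Slc39a14 both up by 4.39, with SEs of 0.47 and 0.62. Hypoxia response genes were split, with 7 of 17 higher and 2 lower (10 and 4 over the list alone; camera adjusted p = 0.0301, 0.0579 without sham 2 and 0.143 after loess scaling; adjusted p = 0.464 with an estimated correlation). Hexokinase 2 (Hk2) and adrenomedullin (Adm) rose by 5.24 ± 0.51 and 5.43 ± 0.75, and the carbonic anhydrase Car9 fell by 1.78 ± 0.24. Heat shock genes were higher in 4 of 15 and lower in 0 (4 and 0 over the list alone; camera adjusted p = 0.0167, 0.0797 without CLP 3, 0.0564 without sham 1 and 0.137 after loess scaling; adjusted p = 0.464 with an estimated correlation). Among them were Bag3 (1.56 ± 0.27), Dnajb1 (4.45 ± 0.80) and Hsp90aa1 (1.24 ± 0.32). Bag3 lost its call without sham 2 and Dnajb1 without CLP 2 (edgeR adjusted p = 0.0545 for Dnajb1). Hsp90aa1 lost its call without CLP 2, CLP 3, sham 1 or sham 2. Without sham 2 the log2 fold changes of Slc7a11, Slc39a14, Adm and Dnajb1 were 5.08, 3.73, 4.58 and 3.62.

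Of 26 genes of fatty acid oxidation, 5 were higher and 1 lower (7 and 1 over the list alone; camera adjusted p = 0.00467, and 0.251 after loess scaling; adjusted p = 0.464 with an estimated correlation). Pdk4, a kinase that blocks entry of pyruvate into the citric acid cycle (gene ID 27273, chromosome 6, 5483351 to 5496278), rose from 181 ± 79.3 to 3973 ± 828 CPM, a log2 fold change of 4.45 ± 0.44 (edgeR adjusted p = 0.00194). The lipoprotein lipase inhibitor Angptl4 rose by 1.77 ± 0.23, the peroxisomal enzyme Ehhadh by 1.68 ± 0.29 and the electron transfer enzyme Etfdh by 1.02 ± 0.29, and the fatty acid binding protein Fabp3 fell by 1.83 ± 0.32. Ppargc1a, a coactivator of mitochondrial biogenesis, was at 44.1 ± 23.4 against 93.3 ± 14.1 CPM and missed the threshold (edgeR adjusted p = 0.0979), passing without CLP 1 (0.0117). None of 24 nuclear genes for OXPHOS subunits was called by edgeR, also adjusted over the list alone, by DESeq2 or by limma-voom, and none had an unadjusted p under 0.05 (camera adjusted p = 0.435), but its direction differed between settings. The list was higher without sham 1 (camera adjusted p = 0.000598), and pointed lower without sham 2 (0.0555) and after loess scaling (0.166). Atp5b stood at 1831 ± 198 against 1200 ± 592 CPM and Atp5a1 at 1638 ± 110 against 1621 ± 681 CPM. Cholesterol synthesis and uptake genes were split, with 3 of 18 higher and 6 lower (4 and 6 over the list alone; camera adjusted p = 0.593). Among them were Msmo1 (2.05 ± 0.31), Fdft1 (1.28 ± 0.23) and Mvd (-1.48 ± 0.32). Msmo1 and Fdft1 lost their calls without sham 2, and Mvd without CLP 2 or sham 1.

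Glucocorticoid response genes were higher in 7 of 18 and lower in 0 (8 and 1 over the list alone; camera adjusted p = 0.0152, 0.0564 without sham 1 and 0.111 after loess scaling; adjusted p = 0.464 with an estimated correlation). The 3 with the smallest p, Mt2, Pdk4 and Cebpd, also belong to other lists. Circadian clock genes changed in both directions, with 5 of 18 higher and 7 lower (7 and 8 over the list alone; camera adjusted p = 0.593; fry mixed adjusted p = 0.00450). By the mixed p of fry 33 of the 35 lists tested passed, so this value does not set the clock list apart. Dbp, a clock output transcription factor, fell from 119 ± 4.15 to 19.8 ± 3.22 CPM (edgeR adjusted p = 0.00118), Per3 from 162 ± 26.7 to 26.2 ± 9.48 CPM and Ciart from 19.9 ± 9.95 to 1.73 ± 0.592 CPM. The log2 fold change of Ciart was -3.52, and -2.90 without sham 2.

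**Figure D2:**
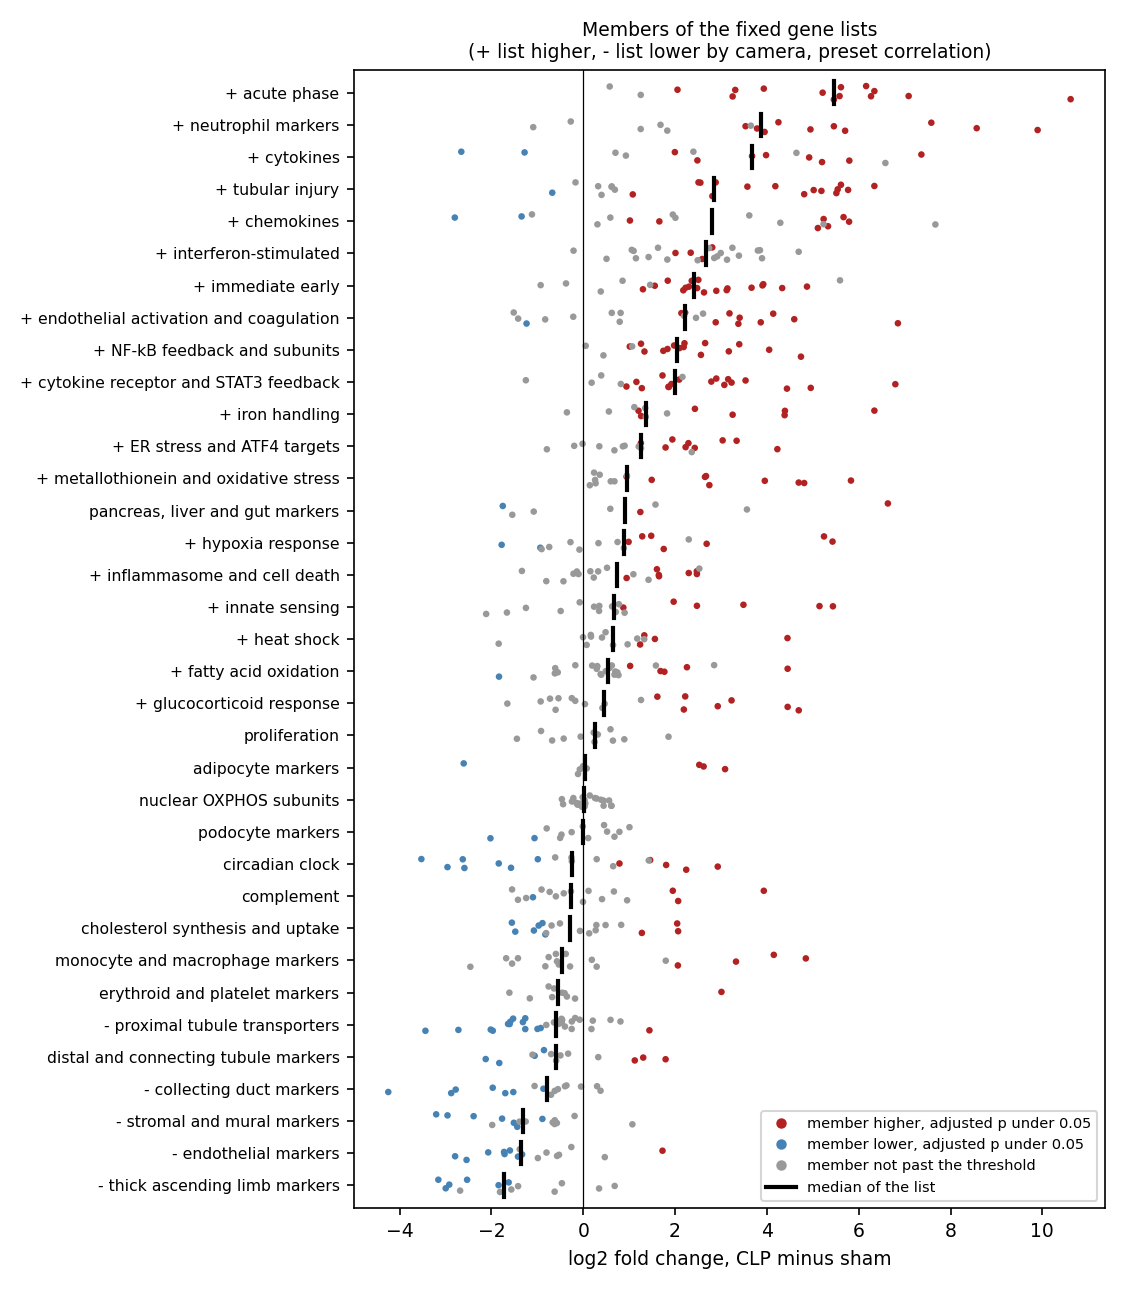
Each row is 1 of the 35 lists tested, ordered by median, and each point is a tested member at its log2 fold change, CLP minus sham (x axis), red or blue where the edgeR adjusted p was under 0.05 and grey otherwise; the bar is the median. The medians run from -1.72 for thick ascending limb markers to 5.46 for acute-phase genes, with 19 lists called higher and 5 lower by camera with the preset correlation.

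Along the nephron, proximal tubule transporters fell in 13 of 30 members and rose in 1 (13 and 1 over the list alone; camera adjusted p = 0.00366; adjusted p = 0.587 with an estimated correlation), although without sham 1 the list missed the threshold (camera adjusted p = 0.214). The glucose transporter Slc2a2 (gene ID 20526, chromosome 3, 28697903 to 28728361) fell from 192 ± 60.9 to 17.7 ± 2.83 CPM, a log2 fold change of -3.44 ± 0.27 (edgeR adjusted p = 0.000974), and the dicarboxylate transporter Slc13a3 by 1.97 ± 0.34. The phosphate transporter Slc34a1 fell from 3947 ± 1605 to 1270 ± 162 CPM (edgeR adjusted p = 0.0133, and 0.0610 without CLP 2), and the amino acid transporter Slc7a9 fell to 84.9 ± 5.85 from 169 ± 3.66 CPM (0.0113, and 0.0640 without CLP 2). Slc5a2, the main glucose transporter of the early proximal tubule, was at 285 ± 111 against 443 ± 203 CPM and did not pass (edgeR adjusted p = 0.254). Thick ascending limb markers fell in 6 of 14 and rose in 0 (11 and 0 over the list alone; camera adjusted p = 0.000729; adjusted p = 0.537 with an estimated correlation). Egf fell from 3062 ± 278 to 994 ± 167 CPM, Ppp1r1a fell by 2.92 ± 0.38 and Sostdc1 fell by 2.99 ± 0.47. Umod, which encodes uromodulin, was at 2773 ± 1099 against 2182 ± 234 CPM (edgeR adjusted p = 0.514). Distal and connecting tubule markers were mixed, with 3 of 13 higher and 4 lower (3 and 7 over the list alone; camera adjusted p = 0.284, and 0.0392 after loess scaling). Emx1 fell by 2.12 ± 0.37 and Wnk4 by 1.06 ± 0.22, and the calcium channel Trpv5 rose by 1.79 ± 0.37. Collecting duct markers fell in 7 of 16 and rose in 0 (7 and 0 over the list alone; camera adjusted p = 0.00401; adjusted p = 0.464 with an estimated correlation). Among them were Hsd11b2 (-1.97 ± 0.25), Fxyd4 (-1.52 ± 0.31) and the intercalated cell anion exchanger Slc4a1 (-4.25 ± 0.71), but the water channel Aqp2 was at 232 ± 128 against 484 ± 452 CPM and did not pass (edgeR adjusted p = 0.351). Of 13 podocyte markers 2 were lower and 0 higher (2 and 0 over the list alone; camera adjusted p = 0.837). Cdkn1c fell by 2.02 ± 0.38 and Magi2 by 1.06 ± 0.28, and Nphs1 was at 15.9 ± 6.97 against 16 ± 12.2 CPM. Slc4a1 lost its call without CLP 2 (edgeR adjusted p = 0.0617), and Trpv5, Fxyd4 and Cdkn1c lost theirs without sham 2. Wnk4 lost its call without CLP 2 or sham 2, and Magi2 without CLP 2, CLP 3, sham 1 or sham 2.

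**Figure D3:**
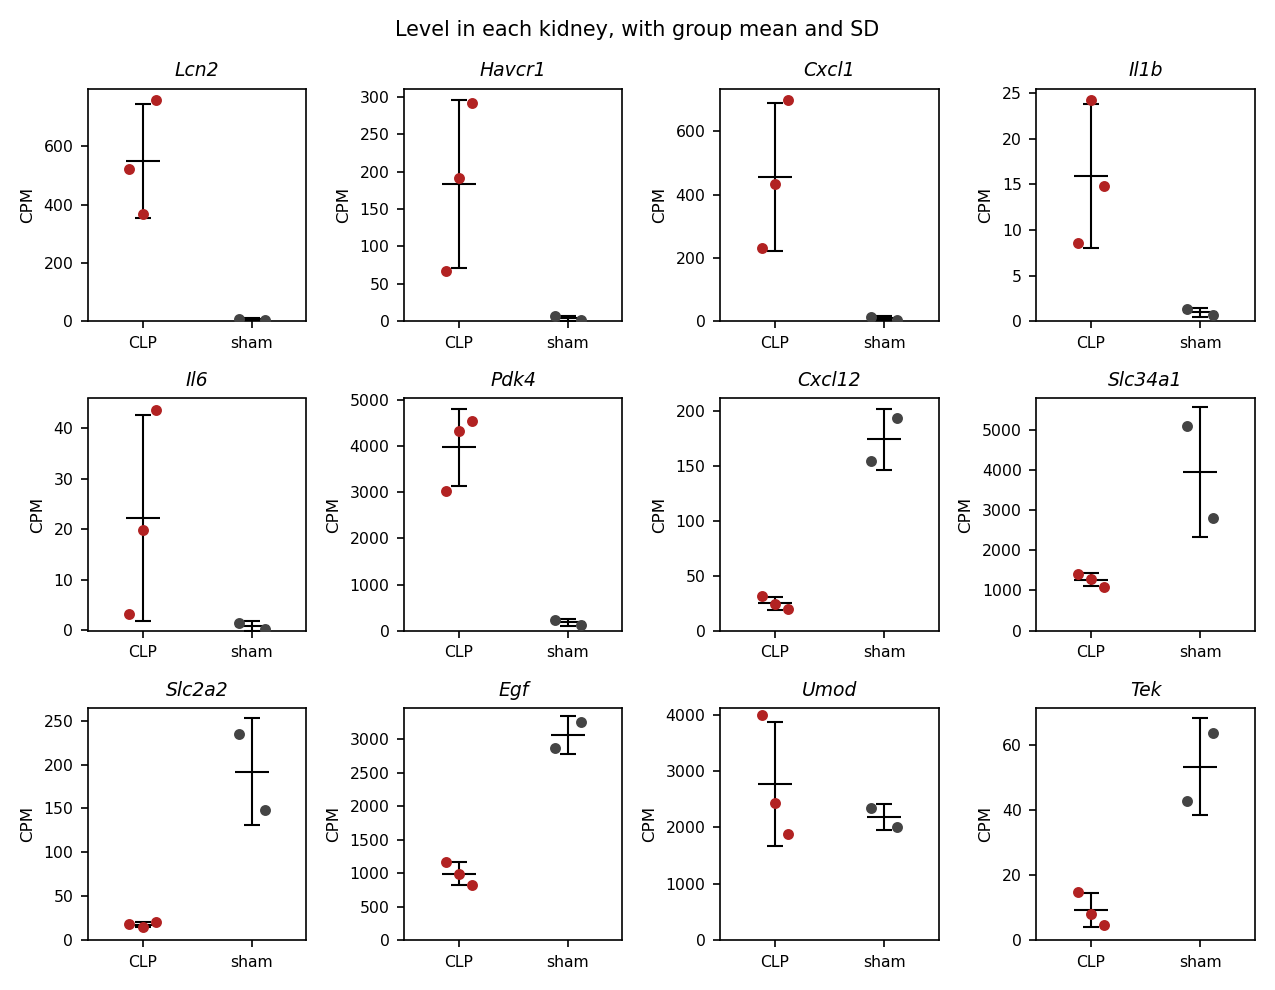
Each point is the CPM of 1 kidney (y axis, from 0 unless the error bar goes lower) in the CLP group (n = 3) or the sham group (n = 2), with the mean as a bar and the SD as error bars. Lcn2 stands at 551 against 6.79 CPM and Slc34a1 at 1270 against 3947 CPM on average, while the groups overlap for Umod.

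Genes of endothelial activation and coagulation were higher in 10 of 21 members and lower in 1 (12 and 3 over the list alone; camera adjusted p = 0.00133; adjusted p = 0.464 with an estimated correlation), with the leukocyte adhesion receptor Icam1 up by 3.38 ± 0.46, the protease Adamts1 by 3.41 ± 0.45 and endothelin 1 (Edn1) by 2.14 ± 0.37. Angpt2, an antagonist of the angiopoietin receptor, was at 4.10 ± 0.524 against 11.7 ± 10.3 CPM and did not pass (edgeR adjusted p = 0.0822). Its log2 fold change was -1.51, and -0.12 without sham 2. Endothelial markers were lower in 8 of 16 and higher in 1 (10 and 1 over the list alone; camera adjusted p = 0.00351; adjusted p = 0.583 with an estimated correlation). Tek, the angiopoietin receptor, fell from 53.3 ± 14.8 to 9.13 ± 5.22 CPM and Tie1 by 1.72 ± 0.33, whereas the nitric oxide synthase Nos3 rose by 1.73 ± 0.27. Stromal and mural markers were lower in 7 of 16 and higher in 0 (7 and 0 over the list alone; camera adjusted p = 0.000368; adjusted p = 0.464 with an estimated correlation). Among them were Itga8 (-3.20 ± 0.35), Myh11 (-1.77 ± 0.33) and the collagen chain Col1a1 (-2.95 ± 0.57). Tie1 and Myh11 lost their calls without sham 2, and Tek and Col1a1 without CLP 2 or sham 2. Without CLP 2 the edgeR adjusted p of Col1a1 was 0.0738.

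Neutrophil markers were higher in 10 of 16 tested members and lower in 0 (11 and 0 over the list alone; camera adjusted p = 5.93e-08; adjusted p = 0.464 with an estimated correlation), with a median log2 fold change of 3.87 that was the same with the 3 members at 0 in sham at their bound. The level of S100a9 reached 4.95 ± 1.52 CPM and Trem1 1.97 ± 0.374 CPM in CLP, and Lrg1, the marker with the smallest p of the list (2.41e-07, unadjusted), is also made by other tissues. Monocyte and macrophage markers were higher in 4 of 18 and lower in 0 (4 and 0 over the list alone; median -0.46, mean 0.31; camera adjusted p = 0.818), with Plac8, Itgam and Cd68 up by 4.15 ± 0.68, 4.85 ± 0.84 and 2.06 ± 0.42. Both Plac8 and Itgam are also carried by neutrophils, and Cd68 lost its call without CLP 2, sham 1 or sham 2. Of 10 erythroid and platelet markers 1, the mitochondrial iron importer Slc25a37, was higher (3.01 ± 0.57) and 0 lower (1 and 0 over the list alone; camera adjusted p = 0.217). Adipocyte markers were mixed, with 3 of 8 higher and 1 lower (3 and 1 over the list alone; camera adjusted p = 0.413). Cidec and Plin4 rose by 2.62 ± 0.68 and 2.53 ± 0.65 and Car3 fell by 2.60 ± 0.53. Of 8 pancreas, liver and gut markers 2 were higher and 1 lower (2 and 1 over the list alone; camera adjusted p = 0.435). They were Apob at 1170 ± 285 against 494 ± 187 CPM, Reg3g with 2 sham counts and a ratio of 126 (95% interval 34.5 to 1042), and Alb at 6.49 ± 0.6 against 21.9 ± 18.8 CPM. Without single kidneys the calls of Cidec, Plin4, Car3, Apob, Reg3g and Alb were lost (highest edgeR adjusted p 0.101, 0.148, 0.0716, 0.165, 0.161 and 0.507, without sham 1, CLP 3, sham 1, sham 2, sham 2 and sham 2). Reg3g rested on CLP 1, without which the ratio was 37.8 (10 to 319). The log2 fold change of Plin4 was 1.81 without sham 1, that of Itgam 4.00 and that of Alb -0.41 without sham 2.

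In 4 lists fewer than 5 members were tested with all 5 kidneys, so that no list test was made with them. Lymphocyte markers reached 5 tested members without sham 1 and 7 without sham 2. The list pointed lower in each of these fits, which hold 1 sham kidney. Of 4 lymphocyte markers, Cd8a was lower (0.563 ± 0.278 against 3.36 ± 2.09 CPM), losing its call without each kidney in turn (highest edgeR adjusted p 0.253, without sham 1). Of 3 adrenal markers, Akr1b7, an aldo-keto reductase, was higher at 14.6 ± 6.17 against 1.95 ± 0.512 CPM. Of 4 sex-specific genes, Kdm5d was lower by 1.15 ± 0.29 (edgeR adjusted p = 0.0263). Kdm5d lost its call without CLP 2, CLP 3 or sham 2. In the structural non-coding RNA list, Snhg11 was the member tested and fell by 1.08 ± 0.20 (edgeR adjusted p = 0.0108, and 0.0512 without CLP 2). The counts adjusted over each of these lists alone were the same.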

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

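All alternatives were planned except loess scaling, which was chosen after the data were seen. Of the edgeR calls, 99.3% were kept with RLE size factors, 99.9% with DESeq2, 96.7% with limma-voom, 79.3% with FPKM values and a pseudocount of 1, and 75.4% with loess scaling. In each of these none was called in the opposite direction. Scaling by library size only gave 1169 genes higher and 2464 lower, which goes with its shift of the median to -0.34. Leaving out each kidney in turn gave 536 to 1955 higher and 382 to 1933 lower, with 25.5% of calls kept without sham 2 and 90.8% without CLP 1. Fewer samples entered these fits, and without sham 1 or sham 2 the lone sham kidney is assumed to vary like the CLP kidneys. The FPKM values gave 557 higher and 814 lower with no filter (40.6% higher), and 40.5% were higher with a pseudocount of 0.1 and a filter. The rows as deposited gave 176 higher and 101 lower of 40774 tested, so that more tests were made on smaller counts. The replicate numbers were taken only as names of the kidneys. With them as a replicate block 1165 genes were higher and 961 lower. Same-numbered kidneys had correlations of deviations from the group mean of -0.134 and -0.109. The deviations of 2 sham kidneys are opposite by design, so CLP 1 with sham 2 and CLP 2 with sham 1 gave 0.134 and 0.109. These correlations thus cannot decide whether the numbers carry a pairing. With the block, the heat shock list had a camera adjusted p of 0.0919.

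With a correlation estimated per list, 0 lists were higher and 0 lower, where 19 and 5 were called with the preset correlation of camera. The fry test called 0 lists lower and 14 higher, and lists it did not call include chemokines (adjusted p = 0.0912), interferon-stimulated genes (0.275) and proximal tubule transporters (0.115). Leaving out kidneys gave 17 to 19 lists higher and 4 to 6 lower. Among the named genes, 45 calls were lost with FPKM plus 1 and no filter, 38 without sham 2, 29 without CLP 2, 23 without sham 1 and 18 with the replicate block. Among all genes called by edgeR, 4 changed sign with each form of the FPKM values, though none was called in the opposite direction there. Among the named genes, the signs that turned belong to 4 genes that did not pass. Nphs1 was at 0.0066 with RLE, 0.0092 with DESeq2, 0.14 with limma-voom, 0.0027 with no filter, 0.55 with the replicate block and 0.19 with loess scaling, and between -0.64 and 1.1 without single kidneys. Atp5a1 was at -0.25 with library size only, -0.00271 with a stricter filter, -0.15 with each form of the FPKM values and -0.40 with loess scaling, and between -0.37 and 0.51 without single kidneys. Umod was at -0.13 with loess scaling and between -0.017 and 0.56 without single kidneys, and Aqp2 between -1.80 and 0.49. The cause of these turns was not tested. Depth limits genes near the floor of 0.111 to 0.145 CPM.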

Other observations

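Gene families by shared symbol start, taken as a description after the data were seen, showed further groups. Of 173 families with at least 10 tested members, 5 were called higher and 4 lower by camera, of which 5 kept the call after loess scaling; with an estimated correlation the adjusted p was 0.938 for each. Genes for cytosolic ribosomal proteins (Rpl and Rps) were higher in 28 of 80 and lower in 0 (median log2 fold change 0.63; camera adjusted p = 1.81e-08), with the smallest p for Rps27, which rose by 1.87 ± 0.21 (SE). Translation initiation genes (Eif) were higher in 24 of 53 and lower in 0 (median 0.71; camera adjusted p = 2.26e-07), among them Eif4ebp1, an inhibitor of cap-dependent translation, at 2.53 ± 0.33 and Eif2s1 at 2.10 ± 0.34. Collagen genes were lower in 15 of 33 and higher in 1 (median -1.28; camera adjusted p = 0.00458), with Col6a3 at -3.53 ± 0.32. N-acetyltransferase genes (Nat) were lower in 7 of 12 and higher in 1 (median -1.61, camera adjusted p = 0.0328). The members with the smallest p were Nat8f1, Nat8f3, Nat8f7, Nat8f4, Nat8f6 and Nat8f5, all called lower. Nat8f1 fell from 365 to 33.8 CPM. These members are close copies between which the counting could split reads. The family call rests largely on them and need not hold for N-acetyltransferases in general. The unmatched gene ID 105246811 stood at 13988 ± 1932 CPM in CLP and 3143 ± 1170 CPM in sham (edgeR adjusted p = 0.01).

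All tests in the paragraphs that follow were chosen after the results were seen. Of the 10 splits of the 5 kidneys into 3 and 2, 1 gave as many genes past the threshold, the real one with 3379. The highest of the others was 0. Each of the others mixed CLP and sham kidneys within a group, so that the CLP difference counted there as spread between kidneys. Few calls in them thus follow from the design, and the 0 does not show how many calls arise without an effect. Besides, 10 splits are too few for a share under 0.05.

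On the first principal component, sham 1 lay between sham 2 and the CLP kidneys. Since this component separated the groups, 1 of the 2 sham kidneys had to lie there. The order alone therefore calls for no special cause. Carry-over of CLP RNA into sham 1 could raise CLP genes there, but it could lower genes that fall in CLP only slightly. The median of 1314 lowered genes was -0.22 log2 units in sham 1 against sham 2 (bootstrap interval over genes -0.25 to -0.18). This lay beyond the -0.06 that the median share of 3.79% over 144 raised genes allows. Of these raised genes, 17 had a sham 1 level below that share of their CLP level. The interval resamples genes within 1 pair of kidneys and measures no spread between mice. Carry-over is thus argued against as the whole cause, but not as a part beside other differences between the 2 sham mice. A mislabelled CLP kidney is argued against by the SD of log2 CPM differences, 0.797 from sham 1 to sham 2 and at least 1.07 to a CLP kidney. A response to the operation that differed between the 2 sham mice stays open and untested.

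By camera with a preset correlation, markers of vessels, stroma, thick ascending limb and collecting duct were lower in CLP. With an estimated correlation none of these 4 lists passed (adjusted p = 0.583, 0.464, 0.537 and 0.464), nor by fry (0.127, 0.0791, 0.0936 and 0.0912). With the kidney as the unit, the mean log2 CPM of the 62 markers differed by -1.35, and by -1.62 to -1.05 without single kidneys (exact 2-sided permutation p = 0.1, the smallest that 3 against 2 kidneys allow). By list, this permutation p was 0.2 for endothelial and for thick ascending limb markers, and 0.1 for stromal and mural and for collecting duct markers. Distal and connecting tubule markers, which are not among the 4 lists, differed by -0.35 with overlapping groups (permutation p = 0.6). A shift that depends on abundance is argued against as the whole cause. Loess scaling removed -0.0460 of this difference (-0.0564 to -0.0356 without single kidneys), and after it the 4 lists had a camera adjusted p of 0.000844, 0.000326, 9.83e-05 and 0.000589 with the preset correlation. The list medians moved both ways with it. They went from -1.32 to -0.94 for stromal and mural markers and from -1.36 to -1.28 for endothelial markers. For thick ascending limb they went from -1.72 to -2.03, and for collecting duct from -0.78 to -0.95. Dilution of all minor cell types would lower podocyte markers alike. The 62 markers fell by more than 13 podocyte markers, with a difference of -1.31, and of -1.52 to -1.16 without single kidneys (exact 2-sided permutation p = 0.1). The kidneys are too few for a p under 0.05, so the permutation test alone cannot decide. The podocyte score differed by -0.044, and by -0.32 to 0.23 without single kidneys, with overlapping groups. For these markers, the values argue against equal dilution of all minor cell types as the whole cause. The 4 lists had been chosen by their calls, and a part played by dilution stays open, as do loss of these cells and less transcript per cell.

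Clock genes moved in both directions. A candidate explanation is that the kidneys of the CLP and sham groups were taken at different times of day. Of 16 tested members of the E-box and ROR-element arms, 14 moved as in a single phase shift, with 9 of 11 lower and 5 of 5 higher. These genes are regulated together and their directions had been seen, so the count carries no p and does not support this explanation over an effect of CLP on the clock. The times of day, and the interval after the sham operation, are not given in the sources used here, so that the explanations cannot be told apart.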
